A study of Mus musculus with 14 samples.

How the data were processed

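Bulk RNA-seq was measured in whole kidneys of 9-week-old mice, 5 h after ischemia-reperfusion (IR) injury or sham surgery. The 12 libraries fall into 4 groups of 3: Control sham, Control IR, VE-PTPiKO sham and VE-PTPiKO IR. VE-PTPiKO is the submitters' name for the genotype that targets VE-PTP, the phosphatase encoded by Ptprb. RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols. Strandedness of the counting is not given in the sources used here, so overlapping and antisense genes were treated as uncertain. The series also lists 2 single-cell samples taken 24 h after injury, which were not analysed here.

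The authors' tools were FastQC, STAR, HTSeq and DESeq2 on the mm10 genome, per the submitters' processing notes, which give no versions. One table was deposited per genotype, comparing IR with sham over 6 libraries. The deposited library columns hold normalized signal: gene counts divided by 1 size factor per library, as the values themselves showed. Group columns hold the mean of these deposited normalized signal values. The deposited log2 fold changes and their standard errors, and the deposited adjusted p-values, were read as the authors' comparison statistics, per the file headers. The size factors were computed separately for each table. Each table had 23493 lines; 182 gene identifiers were listed more than once with identical values, and 23286 were kept. No mitochondrially encoded gene was among them. Multiplying by the recovered factor gave whole reads for 100.0% of values within a tolerance of 0.02. These reads summed to between 15427887 and 21296392 per library, and size factors ran from 0.8863 to 1.2125.

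Each IR versus sham comparison was tested within its own table by limma with a trend on log2(value + 1), for genes with a mean value of at least 1. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The plan made before the data were examined used edgeR for raw counts and this limma test for normalized values. It also stated that the interaction and both genotype contrasts would be pooled over the tables only for raw counts, and otherwise not run. The deposited values are normalized, so running these 3 contrasts departed from that plan, a choice made after the files were seen. They used the recovered reads of all 12 libraries, normalized together by the median of ratios over 14828 genes, with a mean per group in limma. A second interaction test took the difference of both responses as fitted within their own tables. The labels do not say that replicate numbers pair animals or that libraries come from separate animals, so no pairing was used and p-values measure only the spread between these samples. The meaning of the sample codes in the titles is not given. In controls every sham code comes after every IR code, and that of Control IR replicate 1 lies far from the others, while in VE-PTPiKO sham codes lie on both sides of the IR codes. A batch that follows surgery in controls was therefore not excluded.

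The test was checked on simulated counts with 200 genes changed. These counts were drawn independently for each gene around a common mean. They lack the variation shared across genes that the real libraries show, so the rates below may not carry over to them. At a 2-fold change it recovered 76.1% of changed genes for control IR versus sham, 44.8% for VE-PTPiKO IR versus sham, 22.4% for the interaction, 62.7% for the genotype contrast in sham and 71.6% for the genotype contrast in IR. At a 4-fold change the shares were 100%, 93.9%, 92.4%, 98.5% and 100%. False calls were 16 of 150 calls for control IR versus sham, 11 of 110 for VE-PTPiKO IR versus sham, 3 of 80 for the interaction, 10 of 127 for sham and 5 of 128 for IR.

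In total 37 gene lists were fixed before the data were examined, and 524 of their 537 entries matched a gene in the tables. Some lists share genes, such as Fosl1 and Atf3, so counts of lists are not counts of independent results. Lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Alternatives were camera with an estimated correlation and fry. The named genes were also set by rule beforehand: the 10 highest and 10 lowest log2 fold changes among called genes with non-overlapping groups and a mean of at least 5 CPM (counts scaled to the library total), leaving out predicted genes; up to 4 members per list; and Ptprb, Tek, Tie1, Angpt1, Angpt2, Havcr1 and Lcn2. A few genes that this rule names are not reported here. Chance alone gives non-overlapping groups for 10% of genes at 3 against 3.

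Alternatives planned beforehand were another normalization (TMM), no or a stricter low-value filter, other pseudocounts, DESeq2, a replicate block, a 2-fold minimum, 1 model of all libraries, and leaving out each library. Alternatives added after seeing the data were edgeR quasi-likelihood, library weights, a correction for transcript length, the within-table interaction, and leaving out the 3 libraries with the highest Malat1. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.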

Results

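Whole-kidney transcriptomes were compared 5 h after IR injury or sham surgery in Control and VE-PTPiKO mice, with 3 libraries in each of 4 groups. Between 15427887 and 21296392 reads were assigned to genes per library. The comparisons address how the kidney responds to IR in each genotype and whether targeting VE-PTP, a phosphatase that acts on the endothelial receptor Tie2, changes that response.

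Ptprb, which encodes VE-PTP, was read first in every library because it is the targeted gene (mm10, chromosome 10, 116301374 to 116389538). It stood at 168, 245.67 and 177.32 CPM in Control sham, 111.74, 121.57 and 158.5 in Control IR, 117.34, 162.37 and 161.91 in VE-PTPiKO sham, and 75, 94.82 and 125.75 in VE-PTPiKO IR. Group means were 197 ± 42.4, 131 ± 24.7, 147 ± 25.9 and 98.5 ± 25.6 CPM (SD, n = 3). The fitted VE-PTPiKO values on the log2 scale lay 1.34-fold lower in sham and 1.37-fold lower in IR (limma adjusted p = 1 in both). All 3 VE-PTPiKO sham libraries lay below all 3 Control sham libraries, where chance alone gives groups that do not overlap, in either direction, for 10% of genes, and the IR ranges overlapped. Reads over the whole gene cannot show whether a part of it was deleted. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were expressed in all 12 libraries and Xist stayed at or below 1.54 CPM, so sex did not split with the groups.

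**Figure D1:**
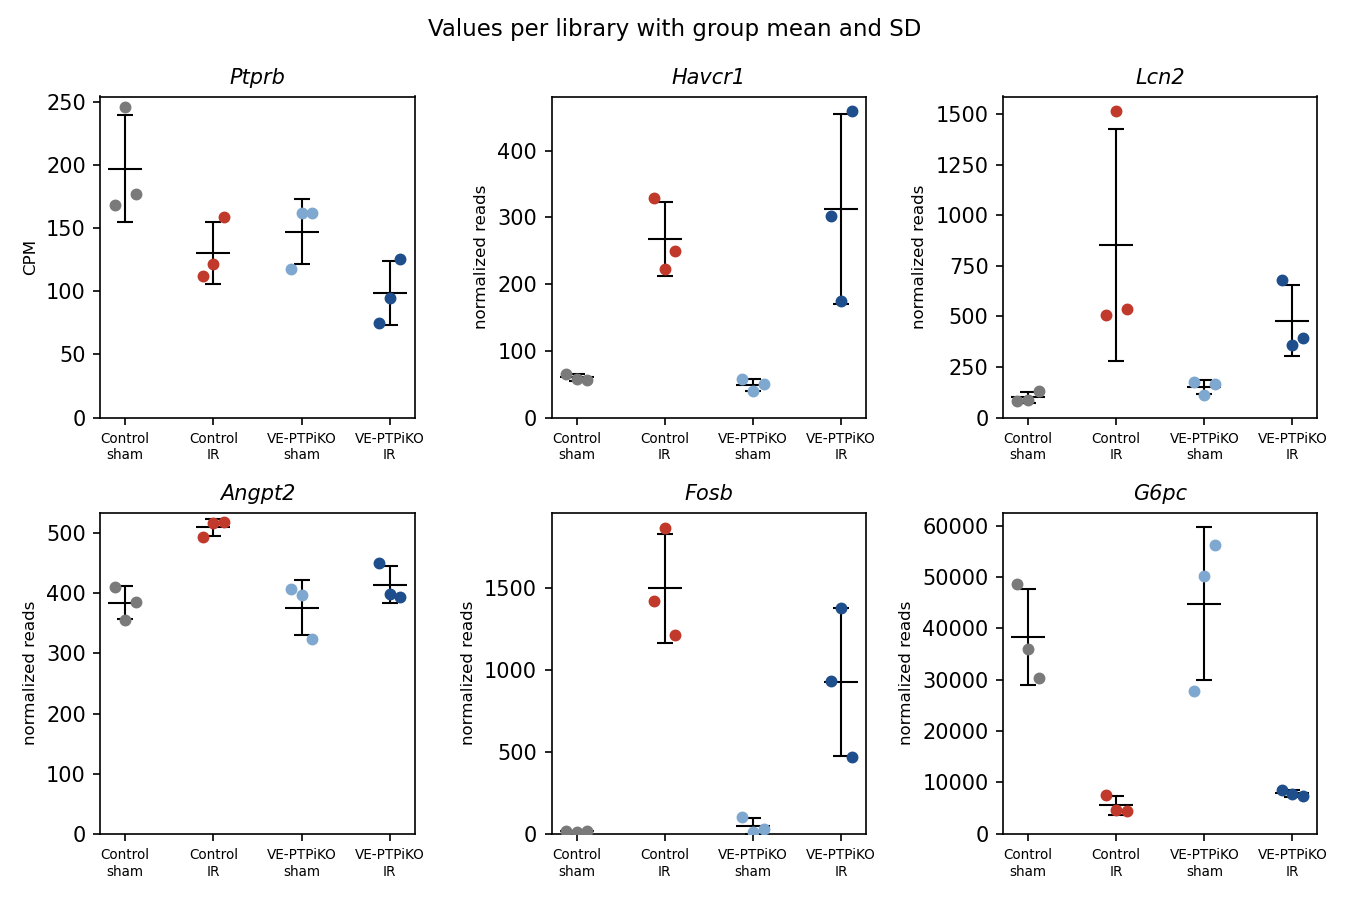
Values of 6 genes in each library (points; replicates 1 to 3 from left to right), with group mean and SD (bars), in CPM for Ptprb and jointly normalized reads for the others. Havcr1 and Fosb were higher and G6pc lower in both IR groups than in their sham groups, while Ptprb ranges of the genotypes overlapped in IR and not in sham.

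In control kidneys, IR raised tubular injury and stress genes and lowered genes of fatty acid oxidation. Krt20, a keratin of injured tubules, rose 93.7-fold (log2 6.55 ± 0.37 SE, adjusted p = 4.09e-06), and the AP-1 gene Fosb rose 91.7-fold (6.52 ± 0.21, adjusted p = 1.41e-07). The kidney injury marker Havcr1 rose 4.35-fold (2.12 ± 0.19, adjusted p = 7.11e-05) and Lcn2 rose 7.6-fold (2.93 ± 0.36, adjusted p = 0.000459). Mmp10, a matrix metalloproteinase listed at 0 in all 3 sham libraries, was at least 81.9-fold higher against a floor of 3 reads per library. Without Control IR replicate 1 this bound was 70.5-fold. G6pc, the glucose-6-phosphatase of gluconeogenesis, was 6.98-fold lower (−2.80 ± 0.22, adjusted p = 3.44e-05). The other genes of largest rise were Fosl1, Atf3, Cxcl1, Chac1, Egr1, Emp1 and Gprc5a, and the others of largest fall were Upp2, Cyp27b1, Igfbp1, Cyp4a14, Hmx2, Lars2, Tmem26 and Aldh1a7. For Fosl1, 57.2% of the gene overlaps the antisense gene Ccdc85b, so its 65.7-fold rise is uncertain.

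By limma, 1870 of 16257 genes passed in control kidneys (1216 up, 654 down; n = 3 per group), 702 of them over 2-fold. Leaving out Control IR replicate 2 lowered the count to 862.

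Tubular injury genes rose together: 21 of 22 passed, and 22 adjusted over the list alone (camera adjusted p = 6.6e-28; adjusted p = 0.136 with an estimated correlation). Sox9 rose 14.2-fold and Krt8 5.91-fold among them. Of 28 immediate early and AP-1 genes, 23 rose and 26 did adjusted over the list alone, with Atf3 up 14.5-fold and Egr2 14.3-fold (camera adjusted p = 5.08e-30; adjusted p = 0.136 with an estimated correlation). Of 18 heat shock genes 16 rose, 17 adjusted over the list alone, including Dnajb1 at 3.21-fold and Bag3 at 2.84-fold (camera adjusted p = 6.17e-16; adjusted p = 0.162 with an estimated correlation). Hspa1a rose 4.17-fold, but it has a near-identical copy, Hspa1b. Of 17 genes of ER stress and the integrated stress response 13 rose and 1 fell, 15 and 2 adjusted over the list alone, with Chac1 up 11.8-fold (camera adjusted p = 2.18e-11; adjusted p = 0.136 with an estimated correlation). Of 19 p53 target and DNA damage genes 10 rose and 2 fell, 11 and 2 adjusted over the list alone, led by Gadd45a at 3.67-fold (camera adjusted p = 6.43e-05; adjusted p = 0.17 with an estimated correlation). Of 16 NRF2 targets 6 rose, 6 up and 1 down adjusted over the list alone, including Srxn1 at 6.96-fold (camera adjusted p = 0.00515; adjusted p = 0.617 with an estimated correlation). The NRF2 call ended without Control sham replicate 2 (adjusted p = 0.15).

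Cytokine and chemokine genes and the list of endothelial activation and adhesion genes rose as well. Reads of whole kidneys do not show which cells gave a change, here or for other lists named after a cell type. Of 26 cytokine, chemokine and NF-kB feedback genes 17 rose, 19 adjusted over the list alone, with the neutrophil-attracting chemokine Cxcl2 up 23.5-fold and Ccl2 16.9-fold (camera adjusted p = 5.1e-16; adjusted p = 0.136 with an estimated correlation). Without Control sham replicate 1 these were 12.7-fold and 10.6-fold, and with a pseudocount of 5 they were 10.4-fold and 9.65-fold (Cxcl2 55.3-fold with 0.1). Il6 was listed at 0 in all Control sham libraries and was at least 9.4-fold higher against the floor of 3 reads per library, or 5.81-fold without Control IR replicate 2. Of 17 endothelial activation and adhesion genes 9 rose, 12 adjusted over the list alone, including the leukocyte adhesion molecules Selp at 5.03-fold and Sele at 2.98-fold (camera adjusted p = 9.36e-08; adjusted p = 0.136 with an estimated correlation). Selp lost its call without Control sham replicate 3, Control IR replicate 1 or Control IR replicate 2, where adjusted p was 0.076, 0.0743 and 0.116. It stood 8-fold higher without Control IR replicate 3. Of 14 coagulation and fibrinolysis genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with F3, which encodes tissue factor, up 6.19-fold and fibrinogen Fga 3.65-fold lower (camera adjusted p = 0.000666; adjusted p = 0.368 with an estimated correlation). In the blood cell lists, 5 of 7 red blood cell genes rose, 6 adjusted over the list alone, with Alas2 up 3.55-fold (camera adjusted p = 1.48e-06; adjusted p = 0.136 with an estimated correlation). The haemoglobin genes Hbb-bs and Hba-a1, with near-identical copies, stood 4.13-fold and 3.94-fold higher. Of 16 monocyte and macrophage genes 3 rose, 4 adjusted over the list alone, with Cd68 up 5.61-fold (camera adjusted p = 0.00383; adjusted p = 0.136 with an estimated correlation). Of 14 neutrophil genes Il1r2 and Clec4e rose, 4 adjusted over the list alone (camera adjusted p = 0.00088; adjusted p = 0.534 with an estimated correlation). Il1r2 lost its call without Control IR replicate 2 (adjusted p = 0.0975), and Clec4e without Control sham replicate 1 or any Control IR replicate (0.0557 to 0.107).

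Fatty acid oxidation and PPARa genes fell: 14 of 21 passed downward and 0 upward, 19 down adjusted over the list alone (camera adjusted p = 4.11e-15; adjusted p = 0.17 with an estimated correlation). Among them, the fatty acid hydroxylase Cyp4a14 was 6.5-fold lower, and Acot1, which has close paralogs, was 3.59-fold lower. Transport and respiration genes did not pass: 0 of 26 proximal tubule transporters and markers and 0 of 18 oxidative phosphorylation genes by limma, with camera adjusted p = 0.655 and 0.254. Among nephron lists also short of the threshold, Kcnj1 was 1.74-fold lower in the loop of Henle list, Klhl3 1.82-fold lower and Trpv5 2.3-fold higher in the distal and connecting tubule list, and Foxi1 1.93-fold lower in the collecting duct list, each past the gene threshold. Camera adjusted p was 0.263, 0.372 and 0.219 for these lists and 0.393 for the podocyte list.

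Among endothelial and Tie2 genes, Ptprb fell 1.54-fold after IR in control kidneys (−0.62 ± 0.15, adjusted p = 0.0246) and Angpt2, a Tie2 ligand made by activated endothelium, rose 1.33-fold (0.41 ± 0.12, adjusted p = 0.0474). Tek, which encodes Tie2, Tie1 and Angpt1 did not pass (log2 −0.26, −0.12 and −0.10). The call of Ptprb ended without Control sham replicate 3, Control IR replicate 1 or Control IR replicate 2 (adjusted p = 0.057, 0.0902 and 0.121) and in the model of all 12 libraries (0.0722), and Angpt2 was called in 8 of 18 settings, failing without any one library. The angiopoietin-Tie pathway list had 1 gene up and 1 down of 12 and the endothelial marker list 2 up and 1 down of 22 (camera adjusted p = 0.322 and 0.438).

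**Figure D2:**
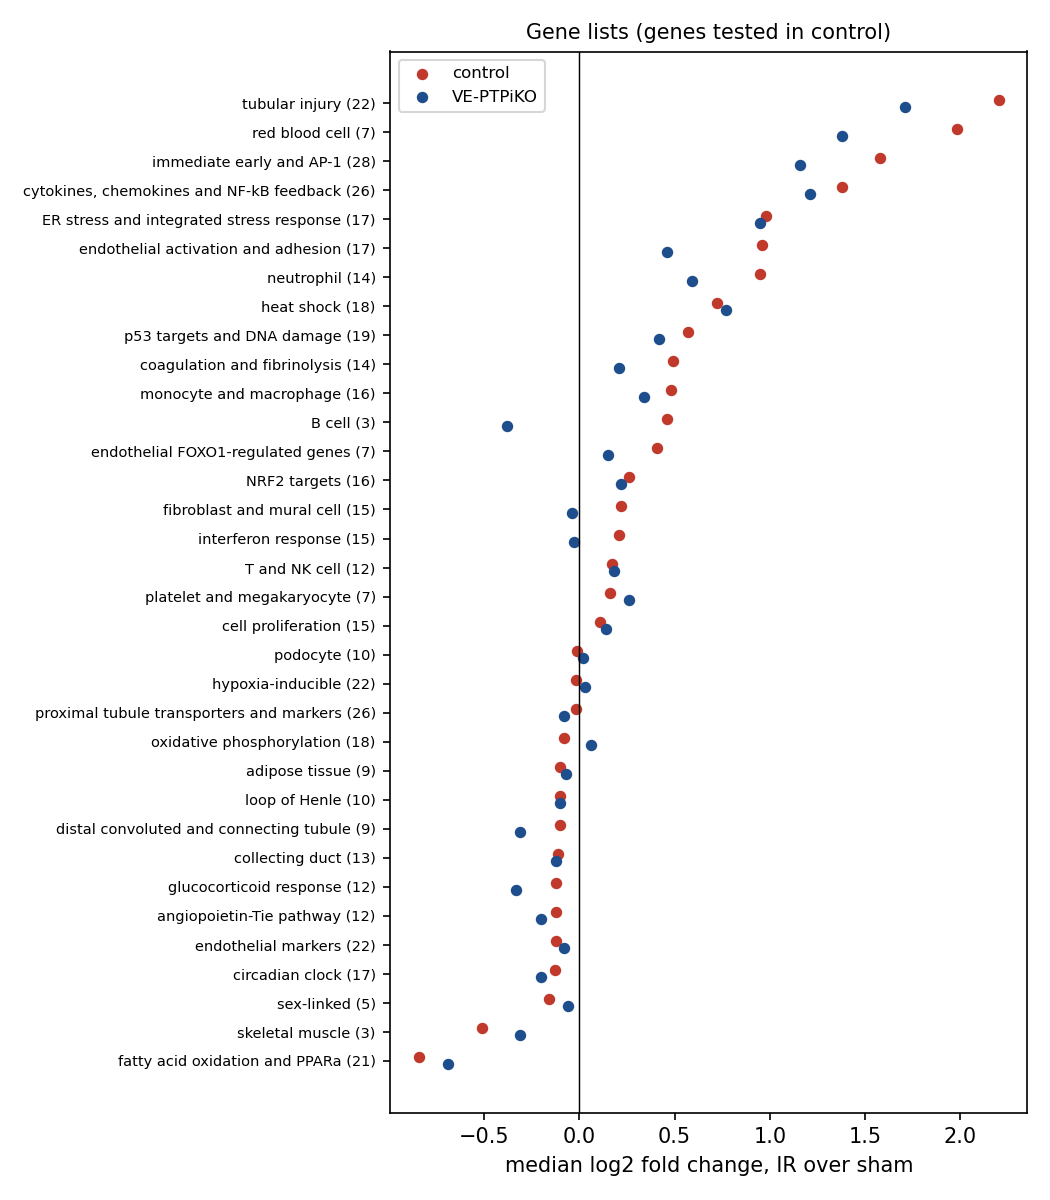
Median log2 fold change of IR over sham for each list with at least 3 tested genes (number tested in control beside its name), in control (red) and VE-PTPiKO kidneys (blue). Tubular injury genes had medians of 2.20 and 1.71, and fatty acid oxidation and PPARa genes medians of −0.84 and −0.69.

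In VE-PTPiKO kidneys, IR also raised tubular injury, AP-1 and chemokine genes and lowered genes of fatty acid oxidation. Krt20 rose 86.6-fold (6.44 ± 0.35, adjusted p = 7.74e-05), the chemokine Cxcl1 13.2-fold (3.72 ± 0.29, adjusted p = 0.000434) and Havcr1 5.89-fold (2.56 ± 0.34, adjusted p = 0.00568). Upp2, a uridine phosphorylase, was 10.1-fold lower (−3.34 ± 0.26, adjusted p = 0.000434). Mfsd4b5, one of a cluster of related transporter genes, was 14.5-fold lower (−3.86 ± 0.19, adjusted p = 5.94e-05), and Control sham replicate 3 was as low as the VE-PTPiKO IR libraries. The other genes of largest rise were Fosl1, Fosb, Egr2, Ch25h, Adamts4, Eps8l3, Atf3 and Emp1, and the others of largest fall were Cyp27b1, Eif4ebp3, Igfbp1, Cyp4a14, Fga, G6pc and Abhd15. Fosl1, Eps8l3, Eif4ebp3 and Abhd15 overlap other genes over 57.2%, 42.4%, 67.3% and 43.0% of their length and are uncertain. Mmp10, again listed at 0 in all sham libraries, was at least 48.3-fold higher against the floor of 3 reads per library. Without VE-PTPiKO IR replicate 1 this bound was 42.2-fold.

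By limma, 445 of 16401 genes passed (315 up, 130 down; n = 3 per group), 305 of them over 2-fold. The count was 1925 without VE-PTPiKO IR replicate 3, and 194, 168, 170 and 126 without IR replicate 1, IR replicate 2, sham replicate 2 and sham replicate 3. VE-PTPiKO IR replicate 3 stood apart from its group: Malat1, a nuclear-retained RNA, took 1.962% of its reads, against 1.152% in VE-PTPiKO sham replicate 2, 1.02% in Control sham replicate 2 and 0.327% to 0.564% in the other libraries. These 3 libraries highest in Malat1 lay at 34.1, 13.9 and 20.9 on the first component within groups (52.4% of that variance), the others from −18.8 to 5.7. Their deviations from the group mean rose with transcript length (Spearman rho = 0.59, 0.44 and 0.59). At the other end, VE-PTPiKO sham replicate 1, VE-PTPiKO IR replicates 1 and 2 and Control sham replicate 1 lay at −18.8, −18.8, −15.3 and −12.6. The deviations of those libraries fell with transcript length (rho = −0.51, −0.55, −0.46 and −0.5). This axis was therefore not limited to the libraries highest in Malat1. Single libraries also ended named calls: Fosb without sham replicate 3 or IR replicate 2 (adjusted p = 0.0689 and 0.0572), Lcn2, up 3.09-fold with all libraries, without sham replicate 2 or 3 (0.0723 and 0.0771), and Igfbp1 and Abhd15 without sham replicate 2 or 3 or IR replicate 1 or 2 (from 0.0612 to 0.133 and from 0.0546 to 0.112).

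**Figure D3:**
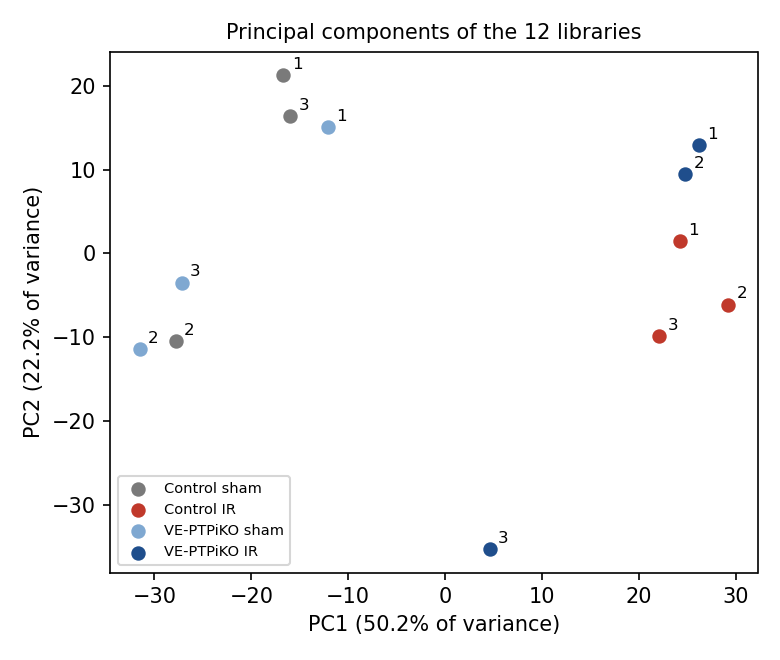
First and second principal components of the 12 libraries (50.2% and 22.2% of variance), coloured by group and numbered by replicate. IR and sham libraries separated on the first component, and VE-PTPiKO IR replicate 3 lay nearest to the sham libraries on it, at 4.6 against 22.1 to 29.2 for the other IR libraries.

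The same lists passed in VE-PTPiKO kidneys by camera, 13 in each genotype. Of 22 tubular injury genes 13 rose, 20 adjusted over the list alone, with Krt8 up 5.73-fold (camera adjusted p = 5.54e-27; adjusted p = 0.0824 with an estimated correlation). Of 28 immediate early and AP-1 genes 17 rose, 23 adjusted over the list alone, with Egr2 up 14.3-fold (camera adjusted p = 7.81e-28; adjusted p = 0.0638 with an estimated correlation). Of 26 cytokine, chemokine and NF-kB feedback genes 14 rose, 17 adjusted over the list alone, with Ccl2 up 14.2-fold (7.41-fold with a pseudocount of 5; camera adjusted p = 1.14e-17), and this list held with an estimated correlation (adjusted p = 0.02). Endothelial activation and adhesion had 3 of 17 genes up, 7 adjusted over the list alone, with Adamts4 8.78-fold higher (5.58-fold without the 3 libraries highest in Malat1), and heat shock 6 of 18, 14 adjusted over the list alone, with Hspb1 2.54-fold higher (camera adjusted p = 1.24e-06 and 1.13e-12; adjusted p = 0.0638 and 0.247 with an estimated correlation). ER stress and the integrated stress response had 8 up and 1 down of 17, 14 and 2 adjusted over the list alone, and p53 targets and DNA damage 5 up and 1 down of 19, 7 and 1 adjusted over the list alone (camera adjusted p = 6.99e-11 and 0.000261; adjusted p = 0.247 and 0.224 with an estimated correlation). Fatty acid oxidation and PPARa had 8 of 21 down, 13 adjusted over the list alone, with Cyp4a14 7.17-fold lower (camera adjusted p = 9.56e-14; adjusted p = 0.247 with an estimated correlation). Coagulation and fibrinolysis had 4 up and 2 down of 14, 6 and 2 adjusted over the list alone, with Fga 6.32-fold lower (camera adjusted p = 0.034; adjusted p = 0.641 with an estimated correlation). Monocyte and macrophage had Cd68 and Cd14 up of 16, and NRF2 targets had Srxn1 up of 16, 2 and 1 adjusted over the list alone (camera adjusted p = 0.0271 and 0.0343; adjusted p = 0.247 and 0.683 with an estimated correlation). Red blood cell genes had 0 of 7 past the limma threshold over all genes and 5 adjusted over the list alone, and neutrophil genes 0 of 15 by either count (camera adjusted p = 0.000211 and 0.0216; adjusted p = 0.493 and 0.426 with an estimated correlation). Hbb-bs was 3.28-fold higher at adjusted p = 0.171. A length correction ended the calls of the NRF2, neutrophil, and monocyte and macrophage lists (camera adjusted p = 0.121, 0.0573 and 0.0672), and a replicate block that of coagulation and fibrinolysis (0.0599). Single libraries ended the calls of NRF2 targets (without sham replicate 2, IR replicate 1 or IR replicate 2; 0.151, 0.168 and 0.0785), neutrophil (sham replicate 1 or IR replicate 1; 0.0519 and 0.0603), coagulation and fibrinolysis (sham replicate 1 or IR replicate 1; 0.157 and 0.0604) and monocyte and macrophage (IR replicate 3; 0.307). Hspb1 lost its call without sham replicate 2 or 3 or IR replicate 1 or 2 (adjusted p = 0.0912 to 0.127), and Cd14 without any library but IR replicate 3 (0.0804 to 0.179). In VE-PTPiKO kidneys Ptprb was 1.57-fold lower after IR (−0.65 ± 0.21, adjusted p = 0.167) and Angpt2 1.11-fold higher (adjusted p = 0.735), neither past the threshold.

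The responses of both genotypes ran in the same direction. Of 1868 genes called in control kidneys and tested in both, 98.6% had the same sign in VE-PTPiKO kidneys. Upward calls shared 303 genes, against 23.9 expected if independent, downward calls shared 117, against 5.3, and 0 genes were called in opposite directions. Across 16021 genes the slope of the VE-PTPiKO on the control log2 fold change was 0.604 (Pearson r = 0.68, Spearman rho = 0.609); genes are not independent replicates, so no p is given, and noise in the control values lowers such a slope. Restricted to genes with a mean of at least 5 CPM the slope was 0.781, and among genes called in control kidneys 0.743. The reverse slope, of control on VE-PTPiKO among genes called in VE-PTPiKO kidneys, was 1.013. These slopes therefore do not settle whether the VE-PTPiKO response was smaller.

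**Figure D4:**
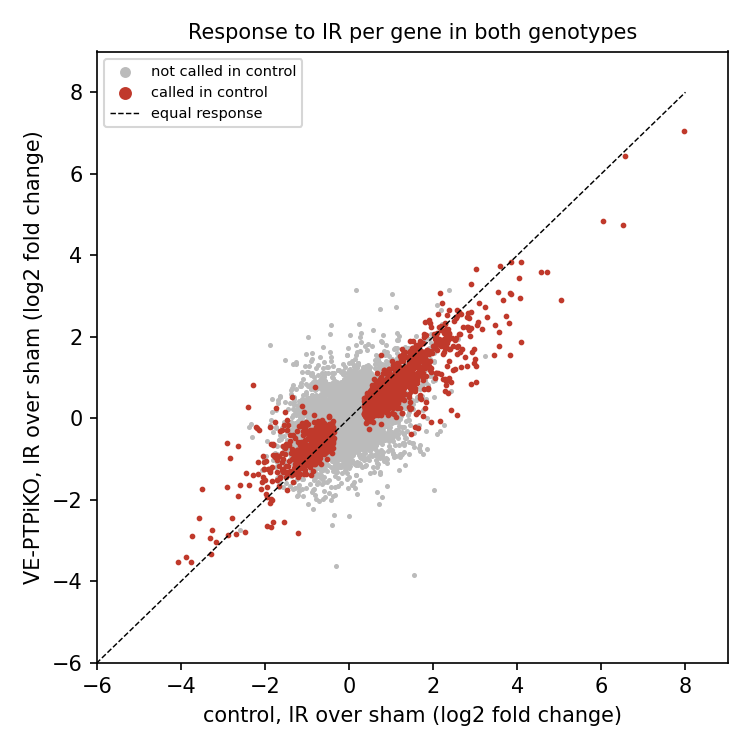
Log2 fold change of IR over sham per gene in control (horizontal axis) and VE-PTPiKO kidneys (vertical axis), with genes called in control in red and the line of equal response dashed. Points called in control lay mostly on the same side of 0 in both genotypes, 98.6% of them.

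The direct test asked whether the IR response differed between genotypes; it and both genotype contrasts were run on recovered reads, a departure from the plan made before the data were examined. The estimated response of Lcn2 was lower in VE-PTPiKO kidneys (log2 difference −1.30 ± 0.54) and that of Havcr1 higher (0.44 ± 0.41). Neither passed the threshold (limma adjusted p = 0.999 in both), and Angpt2 differed by −0.27 ± 0.18. For Lcn2, VE-PTPiKO lay 0.60 higher in sham and 0.70 lower in IR on the log2 scale, the latter from −1.06 to −0.19 under alternatives. Control IR replicate 2 stood at 1515.7 normalized reads of Lcn2, against 507.3 and 537.9 in the other Control IR libraries. By limma 0 of 16339 genes passed, with 432 at an unadjusted p under 0.05 against 817 expected by chance; edgeR and DESeq2 also gave 0, and the within-table test gave 0 with 455. Of the lists, 10 differed by camera, with immediate early and AP-1 genes lower in 25 of 28 (median −0.49, adjusted p = 5.62e-09; adjusted p = 0.625 with an estimated correlation), and none held with an estimated correlation or by fry. Without VE-PTPiKO IR replicate 3 or Control IR replicate 2 the number of lists was 2, and it was 5 without Control sham replicate 2 or VE-PTPiKO sham replicate 1, with the immediate early and AP-1 list called in each omission of 1 library. Simulated differences were recovered for 22.4% of genes at 2-fold and 1.5% at 1.5-fold, in counts that lack the variation shared across genes in these libraries.

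Between genotypes in sham kidneys, fibroblast and mural cell genes lay higher in VE-PTPiKO in 14 of 15 (median 0.27, camera adjusted p = 0.000271; adjusted p = 0.732 with an estimated correlation), 1 of 5 lists that passed. The others were coagulation and fibrinolysis and interferon response, higher, and loop of Henle and oxidative phosphorylation, lower (camera adjusted p = 0.0214 for the first and 0.0465 for each other; adjusted p = 0.732 with an estimated correlation in each). Each of these 4 lost its call without at least 1 single library. Tek, Tie1 and Angpt1 differed by 0.10, 0.10 and 0.16 on the log2 scale (adjusted p = 1 in each). By limma 0 of 16339 genes passed, with 267 at an unadjusted p under 0.05 against 817 expected by chance. With edgeR 0 passed, and DESeq2 gave 1, the fibrinogen gene Fgg (log2 1.65, adjusted p = 0.00495), which was named after its value was seen. Without VE-PTPiKO sham replicate 3 limma called 1 gene, Nmrk1 (−2.16, adjusted p = 0.00686), named likewise. The number of lists was 2 without Control sham replicate 2 and 3 without VE-PTPiKO IR replicate 1, and the fibroblast and mural cell list passed in each such omission.

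Between genotypes after IR, immediate early and AP-1 genes lay lower in VE-PTPiKO in 25 of 28 (median −0.39, camera adjusted p = 9.35e-10; adjusted p = 0.538 with an estimated correlation), and heat shock genes in 16 of 18 (median −0.27, camera adjusted p = 9.11e-07; adjusted p = 0.694 with an estimated correlation), among 11 lists that passed. Endothelial markers lay higher in 17 of 22 (median 0.11, camera adjusted p = 0.0427; adjusted p = 0.694 with an estimated correlation), with Tek at 0.35 ± 0.16 (limma adjusted p = 1). Of the other 8 lists, fibroblast and mural cell, cell proliferation, and fatty acid oxidation and PPARa lay higher (camera adjusted p = 0.00138, 0.0285 and 0.0407), and tubular injury (9.45e-05), endothelial activation and adhesion, cytokines, chemokines and NF-kB feedback, NRF2 targets and red blood cell lower (0.0427 in each of these 4). None of the 8 passed with an estimated correlation (adjusted p = 0.694 to 0.76). Each lost its call without at least 1 single library. A length correction also ended the calls of endothelial activation and adhesion, cytokines, NRF2 targets and fatty acid oxidation (camera adjusted p = 0.0648, 0.056, 0.0527 and 0.0502). By limma 0 of 16339 genes passed, with 709 at an unadjusted p under 0.05 against 817 expected by chance. With edgeR 0 passed, and DESeq2 gave 1, Mfsd4b5 (−4.06, adjusted p = 0.000484). Without Control sham replicate 3 limma called Mfsd4b5 alone in this contrast (−4.05, adjusted p = 1.91e-07) and in the interaction (−4.11, adjusted p = 1.71e-05). Without Control IR replicate 2 the number of lists was 3. It was also 3 without VE-PTPiKO IR replicate 3, where immediate early and AP-1 and fatty acid oxidation remained of the 11. The third, oxidative phosphorylation, had not passed with all libraries and then lay higher in VE-PTPiKO (camera adjusted p = 1.45e-05). Heat shock lost its call without VE-PTPiKO IR replicate 3 (camera adjusted p = 0.155), and endothelial markers without Control IR replicate 1, Control IR replicate 2, VE-PTPiKO IR replicate 2 or VE-PTPiKO IR replicate 3 (0.534, 0.232, 0.124 and 0.283). Immediate early and AP-1 genes kept theirs without each single library.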

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

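The tests of VE-PTPiKO IR replicate 3 on the interaction lists, of transcript length on those lists, of a sham library under the wrong label, of an IR library under the label of Control sham replicate 3, and of the paralogs' gain for Mfsd4b5 were chosen after the results were seen, as was running the interaction at all.

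In the test of the difference between both IR responses, 10 gene lists passed by camera with its preset correlation, and none with an estimated correlation (adjusted p = 0.625 to 0.727 over the 10) or by fry. Adjusted p with the preset was 5.62e-09 for immediate early and AP-1, 0.000454 for coagulation and fibrinolysis, 0.000695 for tubular injury, 0.0133 for endothelial activation and adhesion, 0.0191 for heat shock, and 0.0351 each for cytokines, NRF2 targets, p53 targets, neutrophil and oxidative phosphorylation. The median difference was negative in each except oxidative phosphorylation (median 0.14). For genes that rose this is a smaller rise in VE-PTPiKO kidneys, through lower IR or higher sham values, and for genes that fell a larger fall. In the coagulation and fibrinolysis list, the estimated fall of Fga was larger in VE-PTPiKO kidneys (log2 −2.66 against −1.87 in control). Fga did not pass in the interaction. Its means were 2170 ± 1240 and 3894 ± 1490 normalized reads in Control and VE-PTPiKO sham (SD). After IR they were 537.3 ± 65 and 586.3 ± 52.6. The coagulation and fibrinolysis list lay higher in VE-PTPiKO sham kidneys and was not among those that passed between genotypes after IR.

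Chance was not excluded for these lists: 32 of 100 drawn regroupings gave as many, the highest other giving 19 against the real 10. Only 2 of the 10 lists remained past the threshold without VE-PTPiKO IR replicate 3, so that library may drive much of the difference. However, 2 also remained without Control IR replicate 2. The 2 without VE-PTPiKO IR replicate 3 were immediate early and AP-1 and oxidative phosphorylation (camera adjusted p = 0.000134 and 3.31e-06). Oxidative phosphorylation thus had a smaller p without that library than with it. After a length correction 9 of the 10 remained. That correction takes out only a smooth curve on length in each library. It therefore cannot decide whether variation linked to transcript length lies behind these lists. An effect of the genotype on the response of these lists stays open and untested beyond this.

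VE-PTPiKO IR replicate 3 lay apart from its group. A curve on transcript length took 33.5% of the variance of its deviation. That is under the share set to count for length before this test was run. Noise in that deviation, which no curve can take, was not measured. This test therefore cannot decide how much of the deviation length accounts for. Its median position between sham (0) and the other IR libraries (1) was 0.78 over 284 genes, against a sham library under the wrong label. After a length correction it was 0.89. A value of at least 0.8 was to argue against a smaller injury response in that kidney. It was set before this test was run, but after that library was seen to stand apart. The 0.89 exceeds 0.8 by less than 0.15 (2 SD of this position over the other 5 IR libraries, a margin set after the values were seen), so that explanation stays open.

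Mfsd4b5 (mm10, chromosome 10, 39968153 to 39986646) stood at 128.8, 124 and 95.9 normalized reads in VE-PTPiKO IR and 108.6 in Control sham replicate 3, against 1396.2 to 2082 in the other 8 libraries. Summed over its family the fold was 1.33, but a full loss of Mfsd4b5 would give 1.38, so that test decides nothing, and paralogs gained 3.4% of the lost reads, 55 of 1591 with an SE of 656. Mfsd4b3 stood at 1045.6, 1009.7 and 972.6 in 3 of the 4 low libraries and at 517.7 in the fourth, against 509.6 to 770 elsewhere. A local haplotype that differs between the animals may account for a level that does not follow the groups, but 14.8% of 27 genes within 2 Mb were at an unadjusted p under 0.05, against 15.2% of all genes, which is too few genes to decide. Control sham replicate 3 was not an IR library by its other genes, with a median position of 0.09 between the other Control sham libraries (0) and Control IR (1). Reads shared between paralogs, a haplotype, and a mix-up of animals by genotype or with animals outside the series, which was not tested, stay open.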

How the results depend on the processing

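The alternatives edgeR quasi-likelihood, library weights, length correction, within-table interaction and omission of the 3 libraries highest in Malat1 were chosen after the data were seen, as were all 3 contrasts over 12 libraries. Of 1603 values of 90 named genes in control kidneys under alternatives, 1543 kept direction and call and 60 lost the call; of 1004 values of 56 genes in VE-PTPiKO kidneys, 908 kept both and 96 lost the call. The cause was not tested unless the alternative itself shows it, as a 2-fold minimum or fewer libraries do.

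The control count of 1870 was 702 with a 2-fold minimum, and 862 (without Control IR replicate 2) to 2010 with 1 library left out. The VE-PTPiKO count of 445 was 1009 by DESeq2, 1019 in 1 model of 12 libraries, 3879 with library weights, 746 after length correction, 853 without the 3 Malat1 libraries, and 126 to 1925 with 1 library left out. The genotype count of 0 was 1 by DESeq2 in sham and in IR, 1 in sham without the 3 Malat1 libraries (Rpl3, log2 2.72), and 1 in IR with only the 6 libraries compared (Mfsd4b5). Leaving out 1 library gave 0 to 1 gene for the interaction and both genotype contrasts.

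Called lists with an estimated correlation numbered 0 in control and 1 in VE-PTPiKO kidneys, and 0 in the interaction and both genotype contrasts, where fry also gave 0. Lists called by camera with the preset correlation were also counted with 1 library left out. These ranged from 13 to 15 in control, 10 to 14 in VE-PTPiKO, 2 to 11 in the interaction, 2 to 7 in sham and 3 to 14 in IR. With the same preset and without the 3 Malat1 libraries, lists numbered 2 in the interaction, 3 in sham and 3 in IR. With a replicate block there were 3 in sham, and after length correction 7 in IR.

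The slope of 0.604 was 0.781 at a mean of at least 5 CPM, 0.514 without the 3 Malat1 libraries and 0.531 to 0.664 with 1 library left out. Ptprb in control IR lost its call at −0.62 in the 12-library model and at −0.67 to −0.54 in 3 of the 6 omissions, which spanned −0.74 to −0.46. Signs turned for uncalled genes. In the interaction, Ptprb was 0.02 by edgeR, 0.08 after length correction and −0.20 to 0.15 with 1 library left out; Tie1 was −0.10 to 0.04; Angpt1 was 0.01 by TMM, 0.03 by edgeR, 0.20 with weights, 0.01 after length correction, 0.14 without the 3 Malat1 libraries and −0.13 to 0.10; Havcr1 was −0.02 without the 3 Malat1 libraries. Angpt2 in sham was −0.09 to 0.07, and Havcr1 in IR −0.17 with weights, −0.19 without the 3 Malat1 libraries and −0.20 to 0.50.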

Other observations

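The tests of other splits were planned before the data were examined, but the interaction and genotype contrasts they regroup were run after the files were seen.

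Several further lists did not pass in either genotype by camera, yet held genes that changed. In control kidneys, tested by limma for genes and camera for lists, circadian clock genes went both ways, with Nfil3 up 2.7-fold and Per3 2.21-fold lower (4 up and 4 down of 17, adjusted p = 0.926), as did glucocorticoid response genes, with the metallothionein Mt1 up 3.03-fold (4 up and 4 down of 12, adjusted p = 0.967). Hypoxia-inducible genes had 4 up and 1 down of 22, with the glucose transporter Slc2a1 up 2.42-fold (adjusted p = 0.438). Endothelial FOXO1-regulated genes had 4 up and 2 down of 7, with Apln up 3.8-fold and Cited2 1.89-fold lower (adjusted p = 0.184). The platelet genes Pf4 and Ppbp rose 6.93-fold (4.14-fold with a pseudocount of 5) and 3.57-fold (2 of 7, adjusted p = 0.262), and Ifit3 rose 1.8-fold among 15 interferon response genes (adjusted p = 0.184). Calls ended without 1 library for Per3 (Control IR replicate 2 or 3, adjusted p = 0.0718 and 0.0576, and 0.138 in the 12-library model), Ppbp (Control IR replicate 3, 0.0514) and Ifit3 (Control sham replicate 3 or Control IR replicate 2 or 3, 0.0668, 0.0629 and 0.1). In VE-PTPiKO kidneys the circadian list had 1 of 17 down (Ciart), the glucocorticoid list 4 of 12 up (Mt1, Mt2, Lcn2 and Cebpd), the hypoxia list 2 of 22 up (Adm and Slc2a1), and the FOXO1 list Apln up and Cited2 down of 7, with camera adjusted p = 0.241, 0.817, 0.701 and 0.43. Ciart was called in 7 of 18 settings and lost its call under TMM, no filter, the replicate block, a pseudocount of 5, the 12-library model, the omission of the 3 libraries highest in Malat1, and without any single library but IR replicate 3 (adjusted p = 0.0532 to 0.206). Calls also ended without any library but IR replicate 3 for Apln (adjusted p = 0.0627 to 0.15) and Cebpd (0.0722 to 0.17), without sham replicate 2 or 3 for Lcn2 (0.0723 and 0.0771), without sham replicate 2 or 3 or IR replicate 2 for Cited2 (0.0613 to 0.0689), without sham replicate 2 or IR replicate 1 or 2 for Adm (0.0912 to 0.0926), and without sham replicate 2 or 3 or IR replicate 1 or 2 for Slc2a1 (0.115 to 0.162).

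In the control comparison, 0 genes passed by limma in the lists for T and NK cells (12 tested), B cells (3), fibroblasts and mural cells (15), cell proliferation (15), skeletal muscle (3) and sex-linked genes (5), and 1 passed among 9 adipose tissue genes, Fabp4 at 1.42-fold higher, a call that ended without Control sham replicate 1 or Control IR replicate 2 or 3 (adjusted p = 0.0809, 0.131 and 0.105). Camera adjusted p for these was 0.59, 0.575, 0.935, 0.926, 0.883, 0.792 and 0.926. The adrenal gland list had 1 tested gene, Star (log2 −0.22), and the list of mitochondrially encoded and nuclear-retained RNA had 2, Malat1 (−0.15) and Neat1 (0.51), too few for a list test.

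For 3 against 3 libraries the 10 possible splits are too few for a share under 0.05. In control kidneys 1 of 10 splits gave as many genes, the real one with 1870 and the highest other with 1, and 3 of 10 gave as many lists (13, highest other 14). In VE-PTPiKO kidneys 2 of 10 gave as many genes (445, highest other 1208) and 3 of 10 as many lists (13, highest other 14). The split with 1208 set sham replicate 1 with IR replicates 1 and 2 against sham replicates 2 and 3 with IR replicate 3. Spearman rho of the deviation from the group mean with transcript length was −0.51, −0.55 and −0.46 on the first side. On the other side it was 0.44, 0.23 and 0.59, which points to a structure of the samples along transcript length. What gave rise to it was not tested. At an unadjusted p under 0.05, 58 of 100 drawn interaction splits gave as many genes (432, highest other 5196), so chance was not excluded. In the genotype contrasts 9 of 10 splits in sham gave as many genes (267, highest other 3086) and 7 of 10 as many lists (5, highest other 10), and in IR 5 of 10 gave as many genes (709, highest other 2584) and 4 of 10 as many lists (11, highest other 17). The high counts of other splits in the interaction and both genotype contrasts again point to a structure of the samples. The highest other splits in sham and in IR also parted the libraries by rho with transcript length. In sham, Control sham replicates 1 and 3 and VE-PTPiKO sham replicate 1 (−0.5, −0.26 and −0.51) stood against the rest (0.59, 0.44 and 0.23). In IR, Control IR replicate 1 and VE-PTPiKO IR replicates 1 and 2 (−0.27, −0.55 and −0.46) stood against the rest (−0.11, 0.35 and 0.59).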
